A study of Mus musculus with 6 samples.

How the data were processed

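Expression was measured in 3 samples of superficial masseter, a jaw-closing muscle, and 3 samples of tibialis anterior, a limb muscle, from adult female C57Bl/6 mice aged 6 months. Total RNA from each frozen muscle was amplified, labelled with biotin and hybridised to 1 short-oligonucleotide array per sample, per the labels' protocols. On this array design a gene is read by 1 or more probe sets, each a group of short probes near the 3' end of a transcript.

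The authors deposited 1 linear signal intensity per probe set and array. The submitters' processing notes name MAS5 and GCOS, the array maker's programs, without a version; their settings are not given in the sources used here. Detection calls were not used here. The 2% trimmed mean of the deposited intensity was 150.1 on all 6 arrays, so each array already stood on a common scale and no further scaling was applied. Medians ran from 44.1 to 50.7. The smallest signals lie close to background, where ratios are imprecise, and the number of arrays limits the precision of every comparison. Between 136 and 301 of the signals of an array were at or under 1.

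Probe sets were named through the platform annotation, with symbols checked by gene identifier against a current gene table. Of 22690 probe sets, 64 were controls, 20380 had 1 gene symbol, 691 had several and 1555 had none. The check changed 0 symbols, and 29 symbols that it could not place were kept as given. Only probe sets with 1 symbol were named. A gene was represented by its brightest probe set over all 6 arrays. Mstn, which the rule for named genes lists, is not analysed here because no probe set carried that symbol.

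Signals under 1 were set to 1 and converted to log2. Controls were left out, and a probe set was kept when its mean log2 signal over all 6 arrays reached the 40th percentile of the remaining 22626, a log2 level of 4.84 or a signal of 28.6. This left 13576 probe sets, representing 8316 genes by name. The muscles were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with the replicate number of the sample titles as a fixed block because the study's design text describes paired comparisons. Benjamini-Hochberg adjustment was over all probe sets kept, with a threshold of 0.05 on the adjusted p. Differences are log2 masseter minus tibialis anterior, with limma's standard error (SE). Group means of log2 signal are given as the corresponding linear signal. Where the dimmer muscle's mean lay under the filter level, the fold was computed against that level and is written as "at least". The sources used here do not say whether the 3 samples of a muscle came from separate mice, nor that a number marks 1 mouse. With the block, the p-values measure the spread of the differences within the numbered pairs of these samples, which may be technical in part. Spread among the samples of a muscle that both muscles of a number share does not enter them.

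The lists of genes, the test, the filter, the rule for named genes and the alternatives were fixed before the data were examined. There were 27 lists. Each was named for its theme, and some members are also expressed in other tissues. Those of muscle cells covered fast-fibre genes, slow-fibre genes, developmental and cardiac isoforms, transcription factors of the branchial (head) muscle lineage, positional genes of limb and trunk, myogenic and satellite cell genes, growth and atrophy, glycolysis and glycogen, oxidative phosphorylation, the citric acid cycle, fatty acid oxidation, calcium handling, the dystrophin complex and costamere, and the neuromuscular junction. Those of other tissues and general state covered extracellular matrix, tendon, adipocytes, salivary gland, skin epithelium, erythroid blood cells, endothelium, immune cells, nerve and Schwann cells, smooth muscle and pericytes, immediate-early and stress genes, the circadian clock and ribosomal proteins. The 26 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the members move on balance in 1 direction, were run beside it. Members past the threshold were counted after adjustment over all probe sets and after adjustment over the list alone.

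Genes were named by a fixed rule. It took the 12 genes with the greatest difference in each direction among those past the threshold and alike in sign in all 3 numbered pairs, and up to 4 members of each list with the smallest adjusted p among those past the threshold. It always took Myh1, Myh2, Myh4, Myh7, Myh3, Myh8, Tbx1, Mstn, Igf1, 1 further gene that is not reported here, the Hox genes past the threshold and the 2 brightest members of the adipocyte, salivary, skin, erythroid, tendon, nerve and immune lists. Other genes are said to have been chosen after their values were seen.

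The procedure was tested on simulated data for the 13576 probe sets, with 3 arrays per muscle. Without a simulated effect of the replicate number, the blocked limma test recovered 0% of the changes of 0.585 on the log2 scale, 1.49% of those of 1 and 34.8% of those of 2, with 1 false call among 25. Without the block it recovered 1.49%, 29.9% and 69.7%. A separate simulation, with new noise and new changed probe sets, added a replicate effect of 0.2 SD on the log2 scale. In it the blocked test made 0 calls and the unblocked test 37. A fixed block removes such an effect, and each setting had 1 simulation, so the fall from 25 blocked calls is not put down to the effect. In these simulations the procedure missed many true differences with 3 arrays per muscle. The simulations took each probe set's estimated SD as its true SD, so recovery in the real data may differ. Camera with its preset correlation found 20 of 20 shifted lists of 20 members and called 0 of the unshifted lists. The noise of the simulated probe sets was independent, so this does not show how camera behaves on lists whose members correlate. The ratio of 3' to 5' signal of the Gapdh and Actb control probe sets was taken as a sign of RNA quality and compared between muscles with an exact permutation test, two-sided.

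The alternatives were no replicate block, the block as a random effect, quantile normalization, median centring, no filter, a filter at the 60th percentile, an offset of 10.3 (the 20th percentile of all signals) before log2, eBayes without trend, each replicate number left out, each array left out in a fit without the block, the mean over all probe sets of a gene, and the SAM statistic (significance analysis of microarrays, the test the design text names). SAM was computed from its definition over all 8 sign patterns of the pairs or all 20 assignments of the arrays, at median false discovery rates of 4.96% and 3.79%. A fit without the block and with the mean salivary signal of each array as a covariate was added after the data were seen. Leaving out arrays can also cost power. A call that ends this way therefore does not by itself show dependence on the arrays left out. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 served for annotation and plots.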

Results

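Transcript levels were measured on oligonucleotide arrays in the superficial masseter, a muscle that closes the jaw, and in the tibialis anterior, a limb muscle, of 6-month-old female C57Bl/6 mice. Each muscle was represented by 3 samples on 1 array each, and the comparison asked which genes differ between masticatory and limb muscle. The deposited values were scaled signal intensities with a 2% trimmed mean of 150.1 on every array. Differences below are log2 masseter minus tibialis anterior with their SE and limma's adjusted p, and n = 3 per muscle throughout.

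The masseter held a high level of Myh8, the perinatal myosin heavy chain, with a signal of 4319 against 90.8 in the tibialis anterior. The tibialis anterior held more transcript of the slow-type myosin light chains Myl3 and Myl2 and of the fast IIB heavy chain Myh4. Transcripts of the ankyrin-repeat proteins Ankrd1 and Ankrd2 were also higher there. The Ankrd2 call held in 10 of 19 alternatives and ended without the block. The homeobox gene Irx5 was higher in the masseter, and the homeobox genes Lbx1 and Hoxc4 were higher in the tibialis anterior. The Hoxc4 call held in 7 of 18 alternatives and also ended without the block. In all, 160 of 13576 probe sets passed the threshold, 76 higher in the masseter and 84 higher in the tibialis anterior, and 130 of them differed at least 2-fold. They named 64 genes higher in the masseter and 65 higher in the tibialis anterior, with 0 genes in both groups and 11 probe sets without a gene name. Each of the 160 had the same sign in all 3 numbered pairs. At an unadjusted p under 0.05 there were 1772. Over all probe sets the median difference was 0.02. Pearson correlations of log2 signal across probe sets, which are not independent replicates, ran from 0.921 to 0.951 among masseter arrays, from 0.948 to 0.958 among tibialis arrays and from 0.918 to 0.95 between the muscles. The count moved by more than 1.5 times with eBayes without trend (13 probe sets), with paired SAM (68), with unpaired SAM (67) and in a fit that both leaves out the block and takes the salivary signal of each array as a covariate (64). Leaving out 1 array, in fits that do not match the numbers, gave 75, 45 and 73 probe sets for masseter 1, 2 and 3 and 63, 65 and 58 for tibialis anterior 1, 2 and 3.

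**Figure D1:**
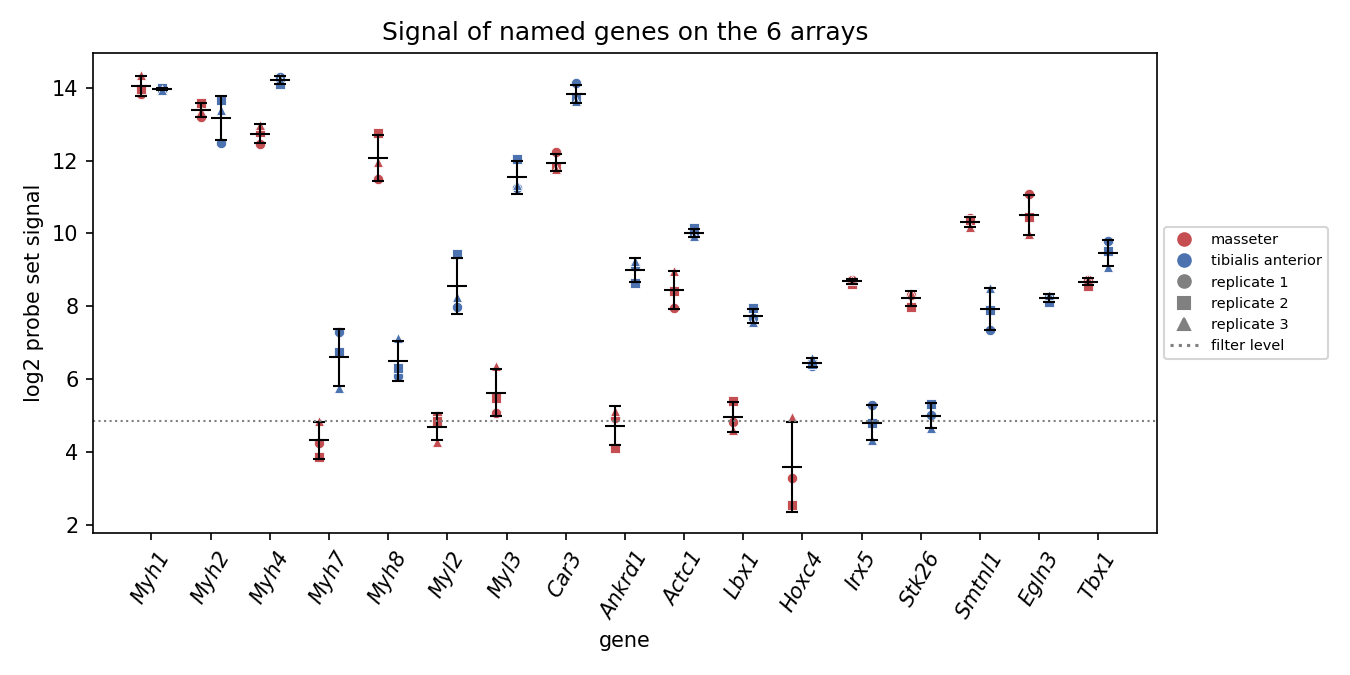
Log2 probe set signal of 17 named genes on the 6 arrays. Points are single arrays (red, masseter; blue, tibialis anterior; circle, square and triangle for replicates 1, 2 and 3), black bars give the mean ± SD (n = 3), and the dotted line is the filter level of 4.84. Myh8, Irx5, Stk26, Smtnl1 and Egln3 sit higher in the masseter, and Myh4, Myl2, Myl3, Car3, Ankrd1, Actc1, Lbx1 and Hoxc4 sit higher in the tibialis anterior.

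Among the slow-fibre genes, those of the isoforms and enzymes typical of slow-twitch fibres, the light chains were much lower in the masseter. Myl3, the slow and ventricular essential light chain, had a mean signal of 49.4 in the masseter and 2979 in the tibialis anterior, a log2 difference of -5.91 ± 0.28 (adjusted p = 7.64e-05). Myl2, the slow and ventricular regulatory light chain, was at least 13.2-fold lower in the masseter, where its mean lay under the filter level (adjusted p = 0.00114). Its call ended with eBayes without trend (adjusted p = 0.062). Car3, a carbonic anhydrase abundant in slow fibres, had signals of 3953 and 14675, a difference of -1.89 ± 0.11 (adjusted p = 0.000225). That call also ended with eBayes without trend (adjusted p = 0.0644). Of the 14 measured slow-fibre genes, Myl3, Myl2 and Car3 were lower in the masseter, 0 were higher and 11 did not pass. Adjusted over the list alone, 6 were lower and 0 higher. The mean difference of the list was -1.20, with a camera adjusted p of 2.4e-06 and an adjusted p = 0.486 with an estimated correlation. The slow heavy chain Myh7 itself did not pass (adjusted p = 0.0671), with a signal of 96.9 in the tibialis anterior and a masseter mean under the filter level. It did pass in 5 of 18 alternatives, which include the fit without the block and that without replicate 3 (adjusted p = 0.00756).

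Among the fast heavy chains, 1 passed the threshold. Myh4, the IIB chain, was lower in the masseter, with signals of 6866 and 19012 and a difference of -1.47 ± 0.14 (adjusted p = 0.00265). The Myh4 call ended with eBayes without trend (adjusted p = 0.155). Myh1, the IIX chain, had signals of 16963 and 16143 (0.07 ± 0.13, adjusted p = 0.877), and Myh2, the IIA chain, had 10712 and 9253 (0.21 ± 0.16, adjusted p = 0.659). The highest signal of an array lay between 18461 and 22667, so these chains were read near the top of the scale, where a difference can be understated, and whether Myh4 differed more than Myh1 was not tested. Actn3, the alpha-actinin of fast fibres, was lower in the masseter by -0.88 ± 0.15 (adjusted p = 0.0342), a call that ended without replicate 2 (adjusted p = 0.0697) and without the filter (adjusted p = 0.138). Of the 17 measured fast-fibre genes, 2 were lower in the masseter, 0 were higher and 15 did not pass. There were 2 lower and 1 higher when adjusted over the list alone. The list's mean of -0.17 had a camera adjusted p of 0.0288 and an adjusted p = 0.614 with an estimated correlation. Its call ended with quantile normalization (adjusted p = 0.866) and without replicate 1 (adjusted p = 0.11).

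Genes of developmental and cardiac isoforms went in both directions. Myh8 had a mean signal of 4319 in the masseter and 90.8 in the tibialis anterior, a difference of 5.57 ± 0.27 (adjusted p = 7.64e-05). Ankrd1, a stress-responsive ankyrin-repeat protein of heart and skeletal muscle, was at least 17.9-fold lower in the masseter (adjusted p = 7.64e-05), and Actc1, cardiac alpha-actin, was lower by -1.56 ± 0.21 (adjusted p = 0.0136). Of 6 measured members, 1 was higher in the masseter, 2 were lower and 3 did not pass. Adjusted over the list alone, 1 was higher and 5 were lower. The list's mean was -0.50 and its median -1.01, with a camera adjusted p of 0.00196 and an adjusted p = 0.51 with an estimated correlation. The embryonic heavy chain Myh3 had signals of 36.4 and 71.7 and did not pass (-0.98 ± 0.34, adjusted p = 0.267).

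Of the positional genes of limb and trunk, Lbx1 and Hoxc4 were lower in the masseter. Lbx1, a homeobox gene of migrating limb muscle precursors, had signals of 30.9 and 213 (-2.78 ± 0.22, adjusted p = 0.00121). Its other kept probe set did not pass. Hoxc4 was at least 3.06-fold lower in the masseter (adjusted p = 0.0458). Its call ended without the filter (adjusted p = 0.0733) and without replicate 1 or 2 (adjusted p = 0.072 and 0.0943), as well as without the block, and it held in 7 of 18 alternatives. Of 9 measured members, 2 were lower in the masseter, 0 were higher and 7 did not pass. There were 4 lower and 0 higher when adjusted over the list alone. The mean was -1.12, with a camera adjusted p of 0.00145 and an adjusted p = 0.503 with an estimated correlation. The probe sets of Hoxa9, a gene chosen after its values were seen, differed. The brighter one did not pass (-0.88 ± 0.42, adjusted p = 0.429), and the other was at least 11.7-fold lower in the masseter (adjusted p = 0.000383). Of the transcription factors of branchial muscle, 0 of 8 measured members passed in either direction, and adjusted over the list alone 1 was higher in the masseter and 1 lower. The list's mean was 0.23 (camera adjusted p = 0.983). Tbx1, which acts in branchial muscle development, had signals of 408 and 707 (-0.79 ± 0.18, adjusted p = 0.0968) and passed only without replicate 3 (adjusted p = 0.0427).

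Other genes with large differences included several enzymes and signalling proteins. Irx5, a homeobox transcription factor, was at least 14.4-fold higher in the masseter (adjusted p = 0.000299). Stk26, a serine/threonine kinase, had signals of 297 and 31.9 (3.22 ± 0.25, adjusted p = 0.00112). Smtnl1, a smoothelin-like protein, had signals of 1280 and 242 (2.40 ± 0.25, adjusted p = 0.00442), and Egln3, a prolyl hydroxylase of hypoxia-inducible factor, had 1456 and 299 (2.28 ± 0.22, adjusted p = 0.00265). With eBayes without trend the Smtnl1 and Egln3 calls ended (adjusted p = 0.138 and 0.135). Khdrbs3, an RNA-binding protein, and Lrrn1, a leucine-rich repeat membrane protein, were higher by 2.48 and 2.44 (adjusted p = 0.00498 and 0.0043). Their calls held in 16 and 13 of 19 alternatives. Dpyd, which starts pyrimidine breakdown, was at least 3.86-fold higher (adjusted p = 0.0256), a call that held in 13 of 18 alternatives. Serpinb1a, a protease inhibitor, was at least 4.23-fold higher in the masseter with an adjusted p of 0.0195, which rose to 0.054 without replicate 2.

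In the other direction, Ankrd2, a stretch-responsive ankyrin-repeat protein, had signals of 334 in the masseter and 2624 in the tibialis anterior (-2.97 ± 0.47, adjusted p = 0.0266). Its log2 signals in tibialis anterior 1, 2 and 3 were 10.28, 10.40 and 13.39, and without tibialis anterior 3, in a fit that does not match the numbers, the difference was -1.96. The Ankrd2 call ended without the block, and it held in 10 of 19 alternatives. Tnfrsf12a, the receptor of the cytokine TWEAK, was lower in the masseter by -2.63 ± 0.24 (adjusted p = 0.00251). In fits that do not match the numbers it was -2.19 without masseter 2 and -3.23 without tibialis anterior 2, and the call, which ended without the block, held in 12 of 19 alternatives. The other kept probe set of Tnfrsf12a did not pass. Myom2, a protein of the sarcomeric M-line, had signals of 274 and 1450 (-2.40 ± 0.16, adjusted p = 0.000383). Peg3, an imprinted zinc-finger gene, had signals of 57.5 and 289 (-2.33 ± 0.19, adjusted p = 0.00129). Padi2, a peptidylarginine deiminase, and Pla2g7, which hydrolyses platelet-activating factor, were lower by -2.44 and -2.42 (adjusted p = 0.00548 and 0.00231). The Padi2 call ended with eBayes without trend (adjusted p = 0.136). The cytokine Il15 was at least 3.66-fold lower (adjusted p = 0.0117), a call that ended without replicate 2 (adjusted p = 0.0843). Of the 38 named genes past the threshold, 9 passed in all of the 19 alternatives that gave values per gene. These were Myh8, Irx5, Stk26, Myl3, Ankrd1, Lbx1, Pla2g7, Myom2 and Peg3. Such calls are on each gene's brightest probe set, and the other kept probe set of Lbx1 did not pass. With eBayes without trend, 28 of the 38 calls ended.

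The list of glycolysis and glycogen genes was lower in the masseter by camera with its preset correlation (adjusted p = 7.66e-08), and did not pass with an estimated correlation (adjusted p = 0.592) or by fry (adjusted p = 0.357). Pfkm, the muscle phosphofructokinase, had signals of 6890 and 11044 (-0.68 ± 0.11, adjusted p = 0.0294), and Gbe1, the glycogen branching enzyme, had 233 and 432 (-0.89 ± 0.16, adjusted p = 0.0491). The Pfkm call ended without replicate 2 or 3 and without the filter (adjusted p = 0.0807, 0.091 and 0.164), and the Gbe1 call without replicate 1, 2 or 3 (adjusted p = 0.0945, 0.115 and 0.112). Of 26 measured members, these 2 were lower, 0 were higher and 24 did not pass. Adjusted over the list alone, 14 were lower and 2 higher. The mean was -0.33. The 3' to 5' signal ratio of the Gapdh control was 2.66 ± 0.23 (SD, n = 3) in the masseter and 1.94 ± 0.11 (SD, n = 3) in the tibialis anterior, with an exact permutation p = 0.1, the smallest that 3 arrays against 3 allow. The ratio of the Actb control was 2.96 ± 0.34 and 2.70 ± 0.11 (SD, n = 3), with an exact permutation p = 0.3.

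Mitochondrial pathways showed small differences. Of the fatty acid oxidation genes, 0 of 26 passed in either direction, and adjusted over the list alone 1 was lower in the masseter. The mean was -0.11, with a camera adjusted p of 0.0243 and an adjusted p = 0.503 with an estimated correlation. That call ended without replicate 2 (adjusted p = 0.1), without replicate 3 (adjusted p = 0.0917) and with quantile normalization (adjusted p = 0.167). Oxidative phosphorylation had 0 of 67 genes past the threshold, a mean of -0.06 and a camera adjusted p of 0.0593. The citric acid cycle had 0 of 17, a mean of -0.08 and a camera adjusted p of 0.374. Adjusted over the list alone, 0 genes of either list passed. Of the calcium-handling genes, 0 of 19 passed, and adjusted over the list alone 7 were lower and 1 higher. Their mean was -0.27, with a camera adjusted p of 0.0243 and an adjusted p = 0.592 with an estimated correlation. The camera call ended without replicate 1 and with quantile normalization (adjusted p = 0.157 and 0.0521). It also ended with the filter at the 60th percentile and with the mean over probe sets (adjusted p = 0.127 and 0.0791).

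**Figure D2:**
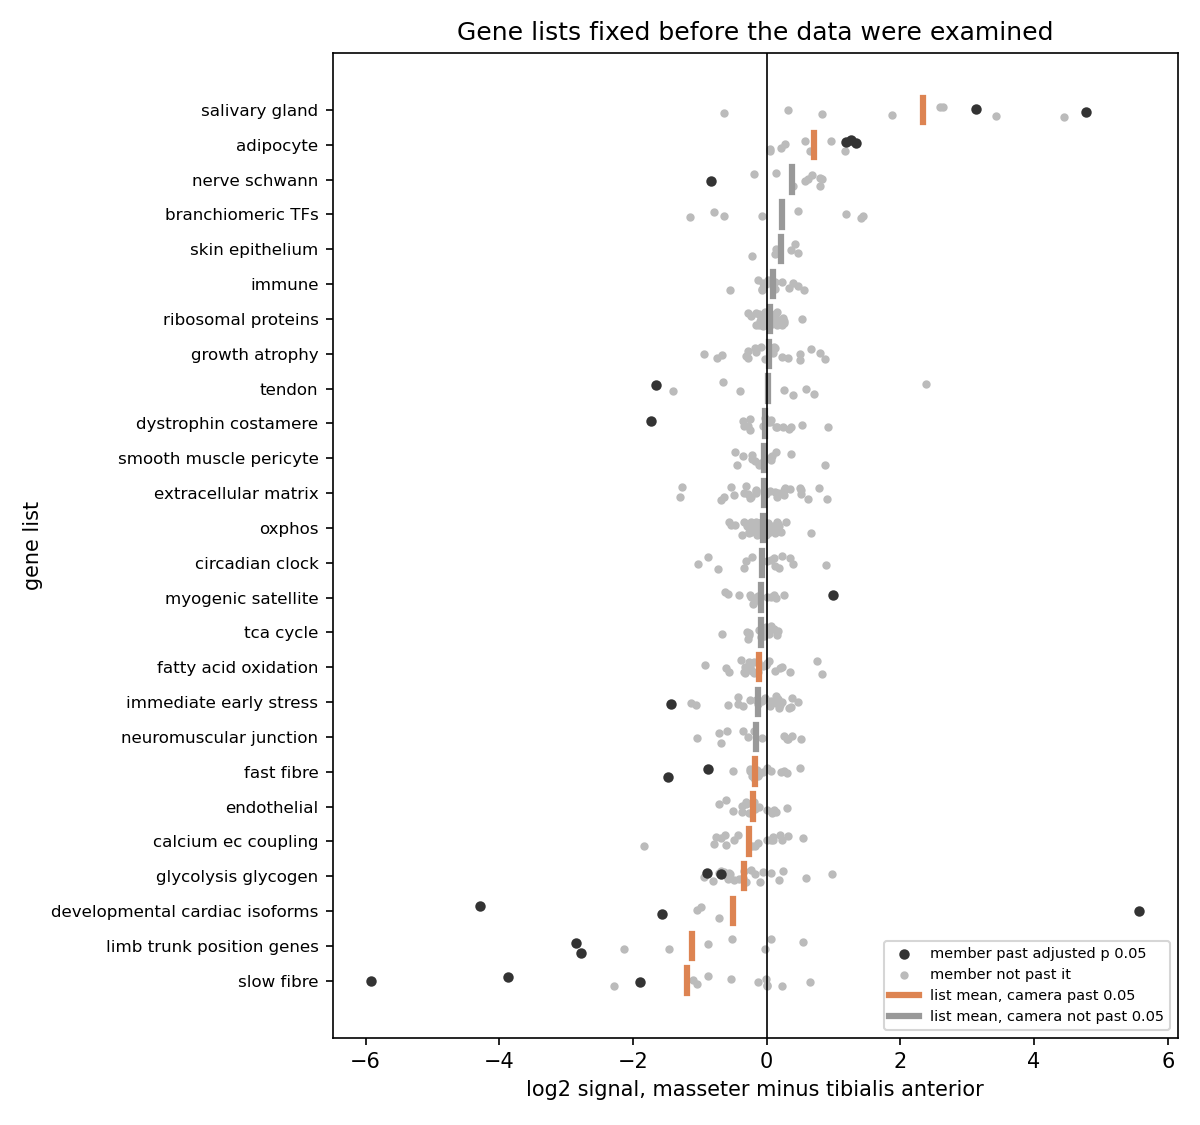
Log2 difference (masseter minus tibialis anterior) of the measured members of the 26 lists tested. Each dot is a gene (black, past an adjusted p of 0.05; grey, not past it; scattered vertically for visibility) and each bar is a list mean (orange, camera adjusted p under 0.05; grey, not). The slow-fibre mean of -1.20 is the lowest and the salivary mean of 2.34 the highest. With an estimated correlation, a test with little power here, 0 of the 26 lists passed.

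Of the salivary gland genes, Pip and Smr3a were higher in the masseter. Pip, a protein secreted in saliva, was at least 16.7-fold higher (adjusted p = 0.0113), and Smr3a, a submandibular gland protein, had signals of 603 and 68.4 (3.14 ± 0.50, adjusted p = 0.0266). Chia1, an acidic chitinase outside the list, was at least 15.6-fold higher (adjusted p = 0.00455). The bounds rest on masseter 1, since without it they are 4.08-fold for Pip and 3.16-fold for Chia1, and without masseter 3 they are 74.5-fold and 66.2-fold. Levels differed widely among masseter arrays, with log2 signals of Pip at 12.98, 9.14 and 4.60 in masseter 1, 2 and 3 and of Chia1 at 13.40, 8.38 and 4.62, so masseter 3 lay under the filter level of 4.84 for both. In fits that do not match the numbers, the log2 difference of Smr3a was 1.07 without masseter 1, 5.06 without masseter 3, 4.37 without tibialis anterior 1 and 2.02 without tibialis anterior 3. These calls rest on differences within the numbered pairs. They ended without the block and held in 8 (Pip), 7 (Smr3a) and 7 (Chia1) of 19 alternatives. For Pip and Chia1 both arrays of pair 3 lay under the filter level. The Chia1 call ended without replicate 1 (adjusted p = 0.0534), the Smr3a call with quantile normalization (adjusted p = 0.0566) and the calls of Pip, Smr3a and Chia1 with the offset (adjusted p = 0.0584, 0.0557 and 0.05001). Of the 10 measured salivary genes, 2 were higher, 0 lower and 8 did not pass. Adjusted over the list alone, 7 were higher and 1 lower. The mean of 2.34 had a camera adjusted p of 1.27e-06 and an adjusted p = 0.503 with an estimated correlation. With single arrays left out, in fits that do not match the numbers, the mean was 0.95 without masseter 1 (adjusted p = 0.148) and 1.70 without tibialis anterior 3 (adjusted p = 0.127). It was highest, at 3.62, without masseter 3. The mean log2 signal of the list was 11.79, 8.78 and 6.44 in masseter 1, 2 and 3 and 7.90, 6.70 and 5.39 in tibialis anterior 1, 2 and 3. The brightest members, Smr2 and the amylase gene Amy1, did not pass (-0.64 ± 0.25, adjusted p = 0.327, and 1.87 ± 0.41, adjusted p = 0.087), although Amy1 passed without replicate 1, 2 or 3, at 1.09, 2.18 and 2.35 (adjusted p = 0.0178, 0.0124 and 0.0259), and Smr2 without replicate 3 (adjusted p = 0.0337).

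Among adipocyte genes, Dgat2, an enzyme of triglyceride synthesis, had signals of 692 and 273 (1.34 ± 0.15, adjusted p = 0.00548). The Dgat2 call ended with eBayes without trend (adjusted p = 0.136), and the gene's other kept probe set did not pass. Adipoq, which encodes adiponectin, and Scd1, a fatty acid desaturase, were higher by 1.26 ± 0.17 and 1.19 ± 0.19 (adjusted p = 0.0167 and 0.0266). Both calls rest on differences within the numbered pairs and ended without the block, holding in 9 and 6 of 19 alternatives, and that of Scd1 also ended without replicate 1, without replicate 3 and with median centring (adjusted p = 0.0504 each). Of 11 measured members, 3 were higher, 0 lower and 8 did not pass, and adjusted over the list alone 7 were higher. The mean of 0.70 had a camera adjusted p of 2.4e-06 and an adjusted p = 0.486 with an estimated correlation. The mean log2 signal of this list was 8.83, 8.47 and 8.27 in masseter 1, 2 and 3 and 7.93, 7.82 and 7.70 in the tibialis arrays, the same ranking by number as the salivary list. The brightest members, Fabp4 and Plin4, were at 0.27 ± 0.16 and 0.05 ± 0.15 (adjusted p = 0.537 and 0.925).

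**Figure D3:**
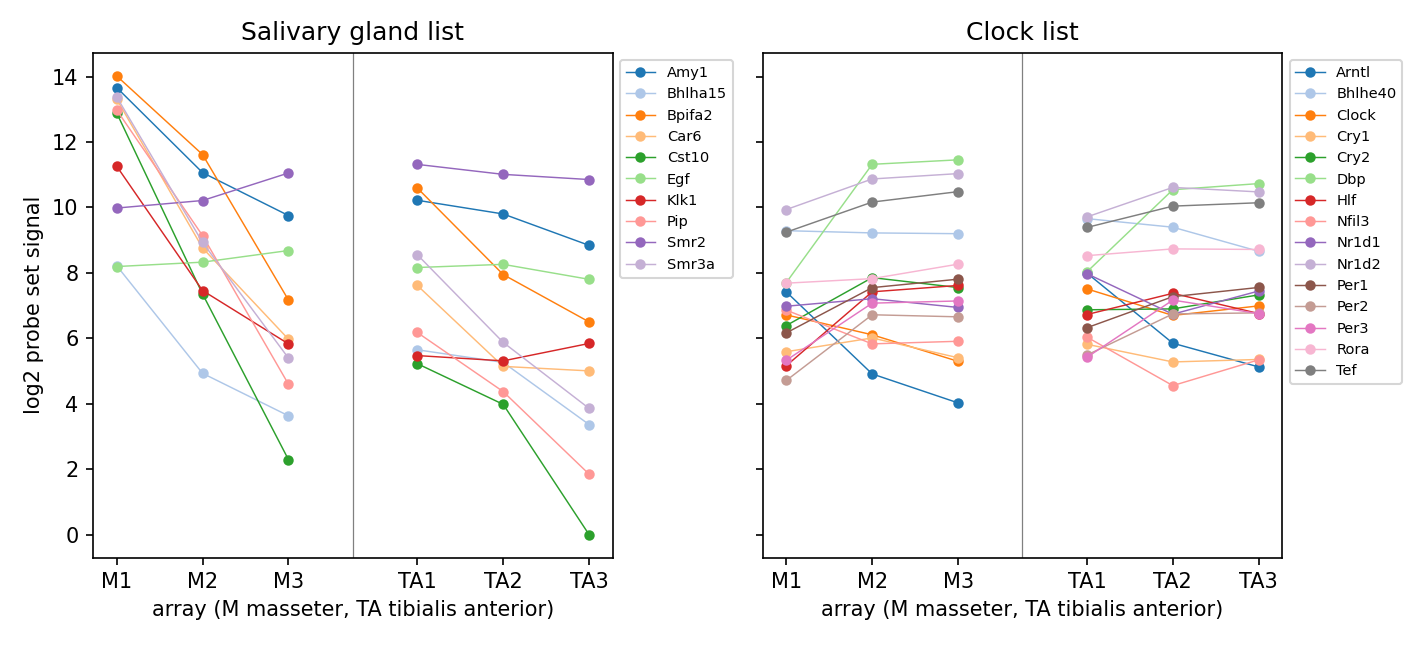
Log2 probe set signal on the 6 arrays (M, masseter; TA, tibialis anterior) of the 10 measured salivary genes (left) and the 15 measured clock genes (right). Each colour is a gene, and lines only join its points within a muscle, since replicates have no order. Most salivary genes are highest in masseter 1, and Dbp is lowest in replicate 1 of both muscles.

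The remaining lists held few calls. Endothelial genes had 0 of 17 past the threshold, also when adjusted over the list alone, and a mean of -0.21 (camera adjusted p = 0.0243, and adjusted p = 0.626 with an estimated correlation). Their camera call ended without replicate 1 (adjusted p = 0.101) and without replicate 3 (adjusted p = 0.317). The 15 myogenic genes included 1 higher in the masseter, the stem cell antigen Cd34 (0.99 ± 0.18, adjusted p = 0.0427), whose call ended without replicate 1 and 2 in turn (adjusted p = 0.0763 and 0.222) and with quantile normalization or median centring (adjusted p = 0.0546 and 0.0705). Tln1, the focal adhesion protein talin, was the 1 of 19 dystrophin and costamere genes past the threshold (-1.73 ± 0.26, adjusted p = 0.0223). The Tln1 call held in 16 of 19 alternatives, and the gene's other kept probe set did not pass. Thbs4, a matrix glycoprotein, was the 1 of 9 tendon genes past the threshold (-1.65 ± 0.25, adjusted p = 0.025), a call that held in 12 of 19 alternatives. Fmod, the brightest tendon gene, was at 0.26 ± 0.21. Prnp, the prion protein gene, was the 1 of 10 nerve and Schwann cell genes (-0.83 ± 0.14, adjusted p = 0.0395), while the myelin gene Mbp was at 0.80 ± 0.18 (adjusted p = 0.0886). The Prnp call ended without replicate 1, 2 and 3 in turn (adjusted p = 0.0563, 0.0736 and 0.118), at differences of -0.84, -0.93 and -0.71. The other kept probe set of Prnp did not pass. Gadd45b, a stress-inducible gene, was the 1 of 25 immediate-early and stress genes (-1.43 ± 0.20, adjusted p = 0.0178), a call that ended without the block and held in 9 of 19 alternatives.

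Neither direction held a call among 21 growth and atrophy genes, 13 neuromuscular junction genes, 29 extracellular matrix genes, 6 skin epithelial genes, 15 immune genes, 14 smooth muscle and pericyte genes, 15 clock genes, 35 ribosomal protein genes or 3 erythroid genes, the last too few to test as a list. Adjusted over the list alone, these gave 1 higher and 1 lower for growth, 0 and 1 for the junction, 2 and 2 for matrix, 0 and 0 for skin, immune and ribosomal genes, 1 and 1 for smooth muscle, 0 and 2 for the clock and 2 and 0 for erythroid genes. The same adjustment gave 3 higher and 2 lower for tendon, 2 and 1 for nerve, 1 and 1 for dystrophin and costamere, 1 and 0 for myogenic and 0 and 2 for stress genes. The camera adjusted p of these lists, the 5 with a single call included, was 0.0804 for nerve and at least 0.426 for the others. The growth factor Igf1 had signals of 136 and 85.9 (0.66 ± 0.24, adjusted p = 0.292). The 2 brightest measured members of the skin, erythroid and immune lists did not pass. The keratins Krt8 and Krt18 were at 0.46 ± 0.28 and -0.21 ± 0.41, and both were highest in masseter 1, as most salivary genes were. The erythroid genes Alas2 and Car2 were at 0.74 ± 0.19 and 0.17 ± 0.23, and the antigen-presentation genes H2-Aa and Cd74 at 0.12 ± 0.20 and -0.13 ± 0.19. Of 14 erythroid genes listed, 8 were on the array and 3 were measured, and of 16 skin genes 6 were measured. These members therefore cannot decide whether the samples differed in skin or blood content. Mean and median differed in sign for the stress (-0.13 and 0.06), clock (-0.08 and 0.07) and dystrophin lists (-0.02 and 0.02), and camera's direction for tendon was down with a mean of 0.02. Of the 26 lists, fry called 2, the positional genes and fatty acid oxidation, both at an adjusted p of 0.0461.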

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

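The fit without the block and with the salivary signal as a covariate (the covariate fit below) was chosen only after the results were seen, and all other alternatives before. Of the 160 probe sets, 116 passed with no replicate block (138 in all), 131 with quantile normalization (133), 136 with median centring (136), 131 with no filter (140), 146 with the filter at the 60th percentile (180) and 147 with the offset (150). Each of them that was tested kept its sign in all of these (146 at the 60th percentile, 160 elsewhere), and 159 did in the covariate fit. With no replicate block and with other filters the differences are the same by construction, so their signs could not change. Of the alternatives just given, the signs were free to change with quantile normalization, median centring, the offset and the covariate. eBayes without trend gave 13 probe sets (3 higher in the masseter, 10 higher in the tibialis anterior) in place of 160 (76 and 84), the covariate fit 64 (28 and 36, against 138 without the block alone), paired SAM 68 (35 and 33) and unpaired SAM 67 (26 and 41); the cause was not tested. Leaving out a replicate number gave 173, 119 and 144. With no replicate block, leaving out masseter 1, 2 or 3 gave 75 (34 and 41), 45 (13 and 32) and 73 (32 and 41), and leaving out tibialis anterior 1, 2 or 3 gave 63 (27 and 36), 65 (28 and 37) and 58 (25 and 33), with fewer arrays. Of 10 lists past the threshold, 5 passed in every alternative that could test them (slow fibre, developmental and cardiac, positional, glycolysis, adipocyte), all with the preset correlation. With an estimated correlation 0 of the 26 lists passed. The slow-fibre list had an estimated correlation of 0.0122, near the preset 0.01, yet its unadjusted camera p went from 3.7e-07 to 0.0374. For glycolysis the estimated correlation was 0.384. A call can thus end through few degrees of freedom, and correlation and lack of power were not told apart. With the preset correlation, 6 lists passed with no replicate block and without tibialis anterior 3, and 5 in the covariate fit.

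The block used numbers that the sources used here do not say mark 1 mouse. Correlations of the same-numbered arrays' deviations from their group means were 0.039, 0.152 and 0.101 over all probe sets, and 4 of 6 arrays correlated best with their own number, as a hint from the data, not the design. With no replicate block 138 probe sets passed (64 and 74), and with the block as a random effect 173. Among named genes, Chia1 (adjusted p = 0.345), Pip (0.302), Smr3a (0.529), Ankrd2 (0.0797), Hoxc4 (0.0539), Tnfrsf12a (0.0631), Adipoq (0.228), Scd1 (0.347) and Gadd45b (0.0805) did not pass with no replicate block, and Myh7 (0.0467) did. In the covariate fit, which also has no block, the differences were 0.79 for Chia1, 1.06 for Pip, 0.57 for Adipoq and 0.34 for Scd1, none past the threshold. These 4 calls had already ended with no replicate block, so their loss is not put down to the covariate. Pip and Smr3a are members of the list whose mean is the covariate, so their values in this fit follow in part from its construction. Dgat2 was at 1.45 (adjusted p = 0.0167).

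Signs reversed for Smr3a in the covariate fit (-0.51) and for genes that had not passed. Leaving out a replicate number gave ranges of -0.0963 to 0.19 for Myh1, -0.0441 to 0.35 for Myh2, -0.065 to 0.12 for Plin4, -0.91 to 0.18 for Krt18, -0.0912 to 0.42 for Car2, -0.12 to 0.37 for H2-Aa and -0.28 to 0.0541 for Cd74. With single arrays left out, Myh1 (-0.0832), Plin4 (-0.15), Krt18 (0.37) and Cd74 (0.0603) reversed without masseter 3, and Krt8 (-0.00991), Car2 (-0.11) and H2-Aa (-0.11) without masseter 1. Myh2 (-0.13) and Cd74 (0.0597) reversed without tibialis anterior 1, Plin4 (-0.15), Krt18 (0.0257) and Cd74 (0.0323) without tibialis anterior 2, and H2-Aa (-0.18) without tibialis anterior 3. The covariate fit reversed Krt8 (-0.11), Car2 (-0.13) and H2-Aa (-0.35), and the mean over probe sets reversed Fabp4 (-0.0143). The cause was not tested. Signal near background limits the genes of low signal.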

Other observations

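The tests below that were chosen only after the result was seen are all those of the salivary and clock genes and, for glycolysis, those of gland dilution and RNA degradation; the matched random lists and the other splits were planned. The genes in the next 2 paragraphs were chosen after their values were seen.

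The log2 signals in tibialis anterior 1, 2 and 3 were 10.30, 9.81 and 13.27 for the LIM protein gene Csrp3, 7.53, 7.38 and 10.17 for the transcription factor Egr1 and 8.40, 6.43 and 9.91 for Fos. Lmcd1, a LIM-domain regulator, was lower in the masseter by -1.88 ± 0.27 (adjusted p = 0.0193), with 11.58, 10.93 and 12.48 in the same arrays. Ccn1, a matricellular protein gene, was lower on both of its probe sets (-1.68 and -2.10, adjusted p = 0.0093 and 0.0299). For the growth factor Hbegf the brighter probe set did not pass (-0.98, adjusted p = 0.113) and the other did (at least 3.94-fold lower in the masseter, adjusted p = 0.0167).

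Among genes higher in the masseter, Ddit4l, an inhibitor of mTOR signalling, passed on both probe sets (1.72 and 2.47, adjusted p = 0.0174 and 0.00709), and Grb14, an adaptor that binds the insulin receptor, was higher by 1.53 ± 0.15 (adjusted p = 0.0033). Deptor, another mTOR inhibitor, passed on 1 probe set (1.47, adjusted p = 0.0427) but not on its brightest (1.61, adjusted p = 0.224). Gpx3, a secreted glutathione peroxidase, was higher by 1.52 ± 0.19 (adjusted p = 0.00983). The imprinted gene Ndn passed on 3 of 5 probe sets (1.13, 1.54 and 1.18), in the opposite direction to the imprinted Peg3.

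Of 10 salivary genes, 8 had their highest value in masseter 1. That count is the pattern itself, so salivary gland tissue in the masseter 1 sample remains open and is not supported by it. The median of masseter 1 minus masseter 3 was 6.14, which is not what steady expression by masseter muscle would give. The tibialis arrays followed the same order, 1 over 2 over 3, in 8 of 10 members, where chance gives 16.7% for each, so gland signal shared by the muscles of one replicate number is a candidate explanation. The members are not independent of each other, and among 26 lists tested for sharing by number the salivary list had an adjusted p of 0.0779.

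Some clock genes differed between replicate 1 and the others in both muscles, and Nr1d1 and Cry1 went opposite ways in the muscles. Dbp had signals of 208.5, 2552 and 2806 in masseter 1, 2 and 3 and 261, 1490 and 1697 in the tibialis arrays. Arntl went the other way, at 171, 30.1 and 16.3 and at 255, 57.7 and 34.9. Across the 15 clock genes the deviations of the number 1 arrays from the others of their muscle correlated at 0.936, above 99.8% of 10000 random lists of matched signal, against 0.072 over all 8316 genes. A time of collection shared by the number 1 muscles is a possible explanation, which the labels do not settle. A random-list test over the 26 lists used another value, the correlation pooled over all 3 numbers, with 1000 random lists per list. For the clock genes that correlation was 0.844, with an adjusted p of 0.0779. The number 1 correlation itself was not adjusted over the lists. It rests on 1 array per muscle set against the others. Clock genes are not independent of each other, unlike genes drawn at random, so the percentile may overstate how rare the correlation is.

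The glycolysis and glycogen list was lower in all 3 pairs, with medians of -0.68, -0.22 and -0.34, and 21 of 26 genes were lower in pair 3, where masseter 3 held little gland signal. Dilution by gland tissue therefore does not account for the difference in pair 3, which rests on 1 array per muscle. The lowest median was that of pair 1, where masseter 1 held the most gland signal, so a contribution of dilution there remains open. The list's median of -0.45 stood at percentile 0 of the matched random lists, whose 2.5th percentile was -0.17, so a general loss of bright transcripts does not account for that median. A difference between the muscles themselves was not tested apart from these and remains open. So does RNA degradation in the masseter samples, since the Actb ratio was above every tibialis array in 2 of 3 masseter arrays and the Gapdh ratio in 3 of 3.

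For the probe sets differing between masseter and tibialis anterior, only 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave 160 calls, and the highest other count was 3. The fits kept the block, but most splits put both arrays of some numbers on the same side. There the difference rests on a single numbered pair, so those counts, the 3 included, are not comparable with the real one. The other splits with each number on both sides gave 0 calls. With 10 splits the share cannot go below 0.1, and among the splits with each number on both sides it cannot go as low. The splits therefore cannot decide on chance.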
